A study of Mus musculus with 39 samples.

How the data were processed

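Chromatin immunoprecipitation and sequencing (ChIP-seq) was used to map H3K4me3, a histone mark of active promoters, and H3K27me3, the mark deposited by Polycomb repressive complex 2, in granule cells of the C57Bl/6J mouse cerebellum at postnatal days 7, 12 and 21 (P7, P12 and P21). Per the labels' protocols, P7 granule cell progenitors were isolated on a Percoll gradient, whereas P12 and P21 nuclei were sorted for NeuN and NeuroD1. Chromatin was sonicated for longer at P12 and P21 than at P7. Comparisons with P7 therefore also compare isolation methods and the cells these select, progenitors against nuclei sorted for NeuN and NeuroD1. P21 against P12 does not. The antibodies were Active Motif 39159 for H3K4me3 and CST 9733 for H3K27me3. Libraries were made with 1 of 2 kits, the TruSeq ChIP or the NEBNext Ultra II kit, with no statement of which library used which. They were read as 75-bp single-end reads on a NextSeq 500.

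The authors deposited 1 table of read counts per gene transcription start site (TSS) for the 21 ChIP libraries and 1 list of peaks for each of the 39 libraries, inputs included. The values of the deposited table were whole numbers whose totals differed between libraries, and they were used as raw counts. The deposited peak lists carry a whole-number score per peak, whose meaning is not given in the sources used here. In the H3K27me3 libraries and inputs of replicates 3 and later that score was 0 throughout. Only the intervals were therefore used, except in an alternative that kept the upper part by score of lists with scores. Per the submitters' processing notes, HOMER 4.11, ChIPseeker 1.30.3 and the mm10 build were used, with no role stated. The aligner, the counting program and the window counted around each TSS are not given in the sources used here.

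Gene IDs of the table were joined to a GRCm38.p6 gene annotation, the assembly of mm10. Of 24045 IDs, 23985 had a record and 60 had none. Coordinates of genes are given on that assembly. 6 genes had missing values in the H3K27me3 columns and were left out of the H3K27me3 fits.

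Counts were compared in R 4.3.3 with edgeR 4.0.16. TSS were kept by filterByExpr, libraries were scaled by the trimmed mean of M-values (TMM), and stages were compared with the quasi-likelihood test (robust fit), with all 3 stages of a mark in 1 fit. P-values are two-sided and adjusted by Benjamini-Hochberg (BH) over all TSS tested, with a threshold of 0.05. The H3K4me3 fit had stage alone. The H3K27me3 fit had stage and the input arrangement, since by the labels replicates 1 and 2 of each stage share 1 input library and later replicates have their own. Gene lists were tested with camera (preset correlation 0.01) from limma 3.58.1, again with an estimated correlation, and with fry, each adjusted over the 15 lists of a contrast. DESeq2 1.42.0 served as a second tool. Log2 fold changes are given with their standard error (SE), and mean counts on the CPM scale of edgeR (library sizes scaled by TMM) with the standard deviation (SD).

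Peak lists were joined with bedtools 2.31.1, Python 3.11.15, pandas 2.3.3 and numpy 2.4.6. A consensus region of a mark at a stage was a stretch covered by peaks in at least 2 libraries. For H3K4me3 this was 2 of 3 libraries at P7 and 2 of 2 at P12 and P21, and for H3K27me3 it was 2 of 5, 4 and 5. A bivalent region was an H3K4me3 consensus region that shared at least 1 base with an H3K27me3 consensus region. A TSS was assigned to a class (both marks, H3K4me3 only, H3K27me3 only or neither) by the consensus regions that overlapped the annotated TSS with 1 kb on either side. That window is not necessarily the one the authors counted, and only 1 TSS per gene was used, so a gene's class and its counts can differ. Peak numbers and covered bases were compared between stages with exact two-sided permutation tests.

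The gene lists, the tests, the rule for naming genes and the alternatives, except those said to be added later, were fixed before the data were examined. In P21 against P7 the rule names the 8 TSS with the largest rise and the 8 with the largest fall for each mark, and the 5 and 5 in the other contrasts. These had an adjusted p under the threshold, a mean of at least 10 CPM in the higher stage and no overlap between the libraries of both stages. Predicted genes, microRNA genes and clone names were passed over. From each list it names up to 4 members past the threshold with the smallest p, and from TSS changed in both marks the 6 per direction pair with the smallest larger adjusted p.

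The contrast between TSS of high and of median count differed between the stages. A lower contrast can come from more background or from a fall of the mark, and these were not told apart. The ratio of the 95th percentile of TSS counts to the median lay between 22.1 and 45.0 in the H3K27me3 libraries of P7 and between 5.00 and 12.9 at P12 and P21. For H3K4me3 it lay between 5.15 and 9.32 at P7 and between 3.00 and 4.32 later. For this reason a second scaling was added after seeing the data: a loess fit (span 0.3) of each library's log2 counts, with 0.5 added, on mean signal, used as offsets, so that each TSS is compared with TSS of similar mean signal. It is called the trended scaling. A fit restricted to TSS with a peak of the mark at any stage was also added then.

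The fits were tested on simulated counts with known answers. With equal enrichment at all stages, P21 against P7 recovered 22% of H3K4me3 TSS changed by 1 on the log2 scale and 71% of those changed by 2, and 36% and 81% for H3K27me3. With lower enrichment at P12 and P21, TMM made 3564 H3K4me3 calls, of which 97.5% were TSS simulated as unchanged, and 6205 H3K27me3 calls, of which 98.4% were unchanged. The trended scaling then made 62 calls (19.4% unchanged) and 104 calls (44.2% unchanged). It recovered fewer of the TSS changed by 1 and 2, 11% and 39% for H3K4me3 and 11% and 47% for H3K27me3, against 23% and 60% and 24% and 61% with TMM. The change of 2 was estimated at medians of 1.07 for both marks, against 1.11 and 0.869 with TMM. Lower enrichment was simulated as a fixed share of reads spread evenly over all TSS. The false change then follows mean signal alone, which the trended scaling is built to remove. How that scaling performs where background varies between TSS was not tested.

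Alternatives were DESeq2, its size factors in edgeR, library totals, no filter on low counts, a minimum absolute log2 fold change of 1, only the compared stages, a block for replicate number, no input arrangement, only replicates 1 and 2 or only later ones, stricter peak overlaps, and leaving out each library in turn. A further alternative for H3K27me3 summed P21 replicates 1 and 2. For each H3K27me3 contrast, 33 of the 126 possible splits of the libraries into groups of the same sizes were also fitted. Intervals for low counts cover counting error only, because reads were not marked by molecule. Input libraries have no column in the count table, so that only their peak lists were used.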

Results

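The data hold 21 ChIP libraries of mouse cerebellar granule cells at 3 stages: P7, when progenitors divide in the external granule layer, P12, when many cells have left the cell cycle and migrate, and P21, when the cells are mature. H3K4me3 was measured in 3 libraries at P7 and 2 each at P12 and P21, and H3K27me3 in 5, 4 and 5 libraries. The question, as the title of the series gives it, is how promoters that carry both marks (bivalent promoters) relate to the timing of granule cell development. Total counts over all TSS lay between 431401 and 5653193 for H3K4me3. By replicate they were 5653193, 543138 and 1461437 at P7, 512122 and 431401 at P12, and 457470 and 2092414 at P21. For H3K27me3 the totals were 925735, 566960, 529047, 2035801 and 1016221 at P7, 432257, 475470, 1052849 and 970711 at P12, and 264093, 310711, 910778, 715341 and 623577 at P21. Spearman correlations across TSS between replicates of 1 group lay between 0.817 and 0.903 for H3K4me3 and between 0.585 and 0.898 for H3K27me3; TSS are not independent replicates.

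Peaks of both marks were found at 3128 of 23985 TSS at P7 (13.0%), 527 at P12 (2.20%) and 316 at P21 (1.32%). Genes of neuronal ion channels and their subunits, most of them voltage-gated, had both marks at 28 of 50 TSS at P7 and at 3 at P21, when 23 had H3K4me3 only. Among genes of mature granule cells and synapses, both marks were found at 19 of 41 TSS at P7 and at 1 at P21, and H3K4me3 alone at 11 and then 23. Genes of progenitors and of the Sonic hedgehog (Shh) pathway, the mitogen of these cells, went the other way: 15 of 31 had both marks at P7 and 2 at P21, and H3K27me3 alone was found at 0 at P7 and 20 at P21. All 39 Hox genes, classical Polycomb targets, had H3K27me3 alone at each stage.

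Of the 3128 TSS with both marks at P7, 1054 had H3K4me3 only at P21, 1020 had H3K27me3 only, 255 had both and 799 had neither. Both marks were present at all 3 stages at 158 TSS, and at any stage at 3243. Gabrd and Cacna1g had H3K27me3 only at P7, both marks at P12 and H3K4me3 only at P21. Cell cycle genes had H3K4me3 only at 26 of 29 TSS at P7 and at 5 at P21. Genes of axon guidance and migration had both marks at 25 of 52 TSS at P7 and at 6 at P21. By regions, 3113 H3K4me3 consensus regions were bivalent at P7 (27.8% of 11192), 527 at P12 (8.01% of 6580) and 275 at P21 (4.71% of 5840). These counts were not tested between stages, and they depend on single libraries: without P7 H3K4me3 replicate 1 or 3 the TSS count at P7 was 1970 or 1982. At P12 it was 836 without H3K4me3 replicate 2 and 190 or 194 without H3K27me3 replicate 3 or 4, and at P21 it was 1218 without H3K4me3 replicate 1 and 208 without H3K27me3 replicate 3. With H3K27me3 peaks of replicates 1 and 2 only, the counts were 1748, 138 and 21. The counts were also lower with a stricter overlap, and at P12 and P21 without peaks that overlap the input, as given further below. A peak in 2 of 3 H3K4me3 libraries was enough at P7 and 2 of 2 were needed later; with a peak in every library of a stage the counts were 896, 138 and 21.

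**Figure D1:**
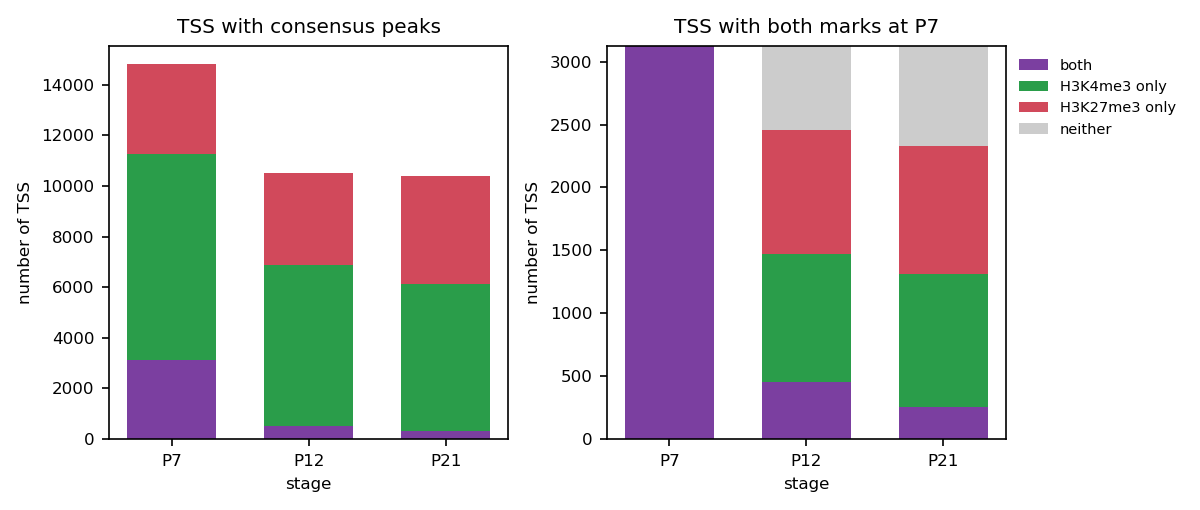
Left, the number of TSS (y axis) with consensus peaks of both marks, H3K4me3 only or H3K27me3 only at each stage; right, the classes at each stage of the 3128 TSS with both marks at P7, with TSS that carried neither mark in grey. There were 3128 TSS with both marks at P7 and 316 at P21, and at P21 those with both marks at P7 were split between H3K4me3 only (1054), H3K27me3 only (1020), neither (799) and both (255).

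From P7 to P21, which differ in isolation and in the cells selected, H3K4me3 fell at most progenitor and cell cycle genes. For these falls, a change with stage and the selection of progenitors at P7 alone cannot be told apart. H3K4me3 rose at 10 of 39 genes of mature granule cells and synapses and fell at 8. Of 18 markers of astrocytes and Bergmann glia 6 were lower too (2 with the trended scaling, 3 without P7 replicate 1, P12 replicate 2 or P21 replicate 2, and 1 without P21 replicate 1). The largest rise was at Cbln3 (gene 56410, chromosome 14, 55878920 to 55884256), a secreted partner of cerebellin made by mature granule cells, from 9.12 ± 3.75 CPM (SD, n = 3) to 58.2 ± 19.3 CPM (SD, n = 2), a log2 fold change of 2.76 (SE 0.39, edgeR adjusted p = 2.26e-09). Grin2c, an NMDA receptor subunit of mature granule cells, rose by 2.32 (SE 0.33), Phyhip by 2.27 (SE 0.27) and Kcnj9, a potassium channel, by 2.24 (SE 0.34). The largest falls included Nhlh1, a transcription factor of newly born neurons, from 185 ± 23.6 CPM to 16.6 ± 0.32 CPM (log2 fold change −3.46, SE 0.31, edgeR adjusted p = 4.17e-25), the cell division genes Cdca5 (−2.48, but −2.20 with adjusted p = 0.0607 without P21 replicate 2) and Cdca3 (−2.42), Igf2bp3 (−2.65) and Zfp36l1 (−2.48).

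Of 31 progenitor and Shh genes, 23 were lower and 0 higher at P21, and the same counts held adjusted over the list alone. Examples were Cxcr4, a chemokine receptor that holds progenitors in the external layer (−2.34, SE 0.33), Ccnd2, a cyclin (−1.97, SE 0.29), Zic4 (−2.28, SE 0.37) and Gli2, an effector of Shh (−1.78, SE 0.30). Of 26 cell cycle genes, 19 were lower and 0 higher (21 and 1 adjusted over the list alone), among them Top2a (−1.92, SE 0.29), Bub1 (−2.03, SE 0.31) and Mki67 (−1.63, SE 0.26). Camera gave adjusted p = 6.56e-14 and 2.84e-13 for these lists, and adjusted p = 0.303 for each with an estimated correlation; with the trended scaling 14 and 11 were lower and the adjusted p with an estimated correlation was 0.0332 and 0.0300. Of 39 mature granule cell and synapse genes, 10 were higher, led by Gabrd, a GABA-A receptor subunit (2.23, SE 0.28), Cbln3 and Grin2c, and 8 were lower (camera adjusted p = 0.261). With the trended scaling 11 were higher and 1 lower (camera adjusted p = 1.27e-07, and 0.0300 with an estimated correlation). Of 48 channel genes, 10 were higher, among them Kcnj9 and Cacna1g, a T-type calcium channel (1.74, SE 0.29), and 3 lower (camera adjusted p = 0.122); with the trended scaling these counts were 15 and 1. Without P21 replicate 1 or 2 the counts of lower genes were 13 or 15 for progenitor and 12 or 11 for cell cycle genes. Those of higher genes were then 4 or 8 for synapse and 3 or 3 for channel genes, and for channel genes 6 without P12 replicate 1 or 2; 3 synapse genes were lower without P7 replicate 1 or P21 replicate 1, and 2 without P21 replicate 2.

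Axon guidance and migration genes were lower at 16 of 50 TSS and higher at 3 (16 and 3 adjusted over the list alone; camera adjusted p = 0.00282, and adjusted p = 0.539 with an estimated correlation). Dcc, a netrin receptor, fell by 1.62 on the log2 scale and Slit3 rose by 1.40 (0.93, adjusted p = 0.138, without P21 replicate 2). With the trended scaling 4 were lower and 5 higher. Genes for writers and erasers of the marks were lower at 16 of 39 TSS and higher at 0 (20 and 1 adjusted over the list alone; camera adjusted p = 0.000136, and 0.432 with an estimated correlation), but with the trended scaling 1 was lower and 1 higher. The Y-linked members of that list, Uty and Kdm5d, were among those lower, and without them 14 of 37 were lower. Whether the sex of the animals differed between the stages was not tested. Without P21 replicate 1 or 2, 6 or 7 axon guidance genes and 3 or 3 writers and erasers were lower; the latter were 10, 8 and 10 without P7 replicate 1, P7 replicate 3 and P12 replicate 2. Among the Hox genes 1 of 24 was higher, Hoxc10 (1.34, SE 0.51), and 0 adjusted over the list alone, but 8 were higher without P7 replicate 2. The call of Hoxc10 was lost in 10 of the alternative analyses: without P7 replicate 1 or 3, P12 replicate 1 or 2, or P21 replicate 1 or 2 the log2 fold change lay between 0.80 and 1.78 and the adjusted p between 0.0762 and 0.401, and with the trended scaling it was 0.19 (adjusted p = 0.838). The list median was 0.81 with TMM and −0.24 with the trended scaling.

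In all, 4844 of 20748 TSS differed in H3K4me3 between P21 and P7, 1864 higher and 2980 lower (edgeR quasi-likelihood, BH). The split depended on the scaling: it was 2549 higher and 1479 lower with library totals and 1326 and 3303 with DESeq2-style size factors. In DESeq2, which gave an adjusted p for 11315 TSS only, it was 207 and 3019. It was 595 and 743 with the trended scaling and 657 and 444 among TSS with an H3K4me3 peak. It also depended on the size of the change, being 1742 higher and 869 lower with a minimum absolute log2 fold change of 1. The median of all TSS was 0.19 with TMM and 0.41 with library totals, and −0.58 in the highest decile of mean signal against 1.04 in the lowest. Without P21 replicate 1 or 2 there were 660 or 1098 calls, without P12 replicate 1 or 2 there were 3113 or 2846, and without P7 replicate 1, 2 or 3 there were 2250, 11444 or 3127. Brd8 (−2.86) and Brca1 were also among the largest falls. Brca1 had 4 counts in all P21 libraries and 159 at P7, a ratio of 0.0756 (95% counting interval 0.0203 to 0.197), and its call was lost without P21 replicate 2 (−2.34, adjusted p = 0.148). Cyp2b9 and Pramel20 were among the largest rises with TMM (2.28 and 2.46), with trended changes of 0.72 (adjusted p = 0.444) and 1.02 (adjusted p = 0.347). Without P21 replicate 1 their calls were lost (1.69 and 2.03, adjusted p = 0.178 and 0.134), and that of Pramel20 also without P7 replicate 1 (1.92) or P21 replicate 2 (2.82). Pramel20 and Fthl17f belong to multi-copy families with similar sequences, and their values are uncertain.

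**Figure D2:**
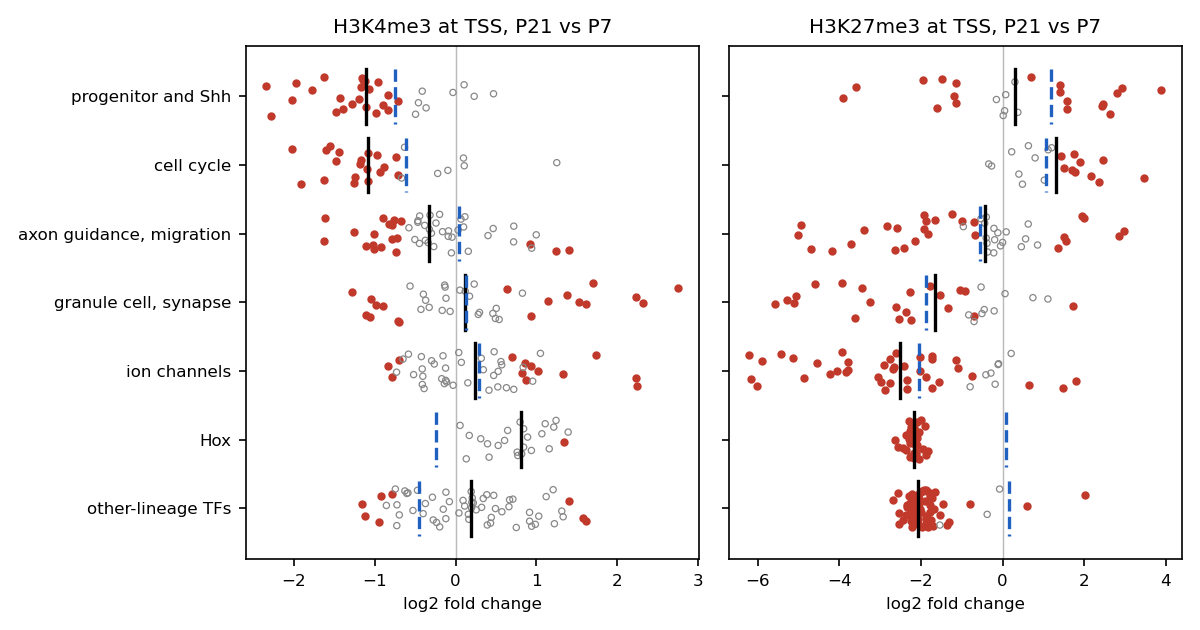
Log2 fold change (x axis) of H3K4me3 (left) and H3K27me3 (right) at the TSS of each tested member of 7 gene lists, P21 against P7, with called members in filled red and others in open grey; black lines are list medians with TMM and blue dashed lines the medians with the trended scaling. H3K27me3 medians of channel genes (−2.51 and −2.06) and synapse genes (−1.66 and −1.88) lay below 0 with both scalings, and that of Hox genes (−2.17 and 0.08) with TMM only.

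Between P7 and P12, which also differ in isolation and in the cells selected, H3K4me3 fell at many progenitor and cell cycle genes. Markers of other cell types were also called in this contrast, such as Sox9, Foxp2, Kit and Lhx1. Nhlh1 fell the most (log2 fold change −3.89, SE 0.37, edgeR adjusted p = 3.08e-21), from 185 ± 23.6 CPM (n = 3) to 12.4 ± 1.42 CPM (SD, n = 2), and Cbln3 rose by 2.56 (SE 0.42). Of 31 progenitor and Shh genes 17 were lower (19 adjusted over the list alone) and 0 higher, with Gli2 at −1.89, Cxcr4 at −1.95 and Nfia, a transcription factor, at −2.30. Of 26 cell cycle genes 16 were lower (21 adjusted over the list alone) and 0 higher, with Top2a at −1.96, Cdk1 at −1.89 and Rrm2 at −1.62. Among synapse genes 8 of 39 were higher, including Gabrd (2.12) and Grin2c (2.48), and 2 lower. Among channel genes 7 of 48 were higher, including Cacna1g (1.74) and Kcnj9 (2.42), and 3 lower. Without P12 replicate 2 the calls of Cbln3 (1.72, adjusted p = 0.193), Gli2 (−1.80, 0.0575), Nfia (−1.82, 0.119) and Top2a (−1.76, 0.0556) were lost. The list counts fell with either P12 library left out: without replicate 1 or 2, 7 or 1 progenitor and 6 or 2 cell cycle genes were lower, and 6 or 3 synapse and 3 or 3 channel genes were higher (3 channel genes also without P21 replicate 1). Without P7 replicate 2, 8 synapse and 8 channel genes were lower.

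Camera adjusted p was 4.62e-13 for progenitor genes and 2.31e-14 for cell cycle genes, and 0.351 for each with an estimated correlation. With the trended scaling 7 of the progenitor and 8 of the cell cycle genes were lower and 0 higher (adjusted p = 0.0245 and 0.0151 with an estimated correlation), and 10 synapse and 11 channel genes were higher and 0 lower (0.0151 and 0.0217). Axon guidance genes (9 lower, 3 higher of 50) and writers and erasers (10 lower, 0 higher of 39) also passed camera (adjusted p = 0.00311 and 3.09e-05), but with an estimated correlation their adjusted p was 0.590 and 0.370. Of the axon guidance genes 2 were lower and 3 higher with the trended scaling, and of the writers and erasers edgeR called 0. The writers and erasers called with TMM included the Y-linked Uty, with 10 counts at P12 against 406 at P7 (ratio 0.200, 95% counting interval 0.0951 to 0.371). Without P12 replicate 1 or 2, 4 or 0 axon guidance genes (17 without P7 replicate 2) and 4 or 0 writers and erasers were lower; the latter were 19, 5 and 6 without P7 replicate 2, P7 replicate 3 and P21 replicate 2, and 8 of 37 without the Y-linked members. In all, 3018 of 20748 TSS were called, 1108 higher and 1910 lower. The split was 1364 and 856 with library totals (median of all TSS 0.37 against 0.16) and 367 and 328 with the trended scaling. In DESeq2, which gave an adjusted p for 10855 TSS only, it was 181 and 1831. It was 429 and 212 among TSS with a peak, and 1028 and 732 with a minimum absolute log2 fold change of 1. Without P12 replicate 1 or 2 there were 371 or 69 calls, and without P7 replicate 1, 2 or 3 there were 1693, 8191 or 1694. Low-count genes among the named falls were Slc39a7 (2 counts at P12 against 142 at P7, ratio 0.114, 95% counting interval 0.0137 to 0.421), Cks1b, a cyclin-dependent kinase partner (3 against 212, ratio 0.115, interval 0.0235 to 0.340), Brca1 (2 against 159, ratio 0.102, interval 0.0123 to 0.375) and Brd8 (5 against 321, ratio 0.126, interval 0.0408 to 0.298). Of the named rises, Rhox2c, Cdh16 and Lhfpl1 had trended adjusted p = 0.204, 0.298 and 0.421, and Rhox2c and Magea4 belong to multi-copy families, so that their values are uncertain. The calls of Slc39a7, Cks1b and Brca1 were lost without P12 replicate 1 (−2.21, −3.59 and −3.20) and replicate 2 (−8.11, −2.90 and −3.48), those of Brd8, Rhox2c, Cdh16, Magea4 and Lhfpl1 without P12 replicate 2 (−2.53, 2.32, 2.33, 1.96 and 2.22), and that of Lhfpl1 also without P12 replicate 1 (2.66) and P7 replicates 1 and 3 (2.01 and 2.26).

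H3K4me3 did not differ detectably between P12 and P21, where cells were isolated alike. Gabrd had 110 ± 22.7 CPM at P12 and 115 ± 21.03 CPM at P21 (SD, n = 2 each), and Cacna1g had 93.96 ± 15.6 and 94.4 ± 2.98 CPM. The list medians were −0.08 for progenitor genes, −0.04 for cell cycle genes, −0.12 for synapse genes and 0.04 for channel genes. edgeR called 0 of 20748 TSS, with 206 at an unadjusted p under 0.05. DESeq2 called 0, with 57 unadjusted, and edgeR with library totals or the trended scaling called 0, with 276 and 540 unadjusted.

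H3K27me3 fell from P7 to P21 at most channel and synapse genes and rose at 10 of 20 cell cycle genes, while progenitor genes went both ways. All 9 markers of unipolar brush cells and cerebellar nuclei were lower as well (7 with the trended scaling), 1 of which, Calb2, is also in the synapse list. At Cacna1g (gene 12291, chromosome 11, 94408391 to 94474400) the signal went from 814 ± 142 CPM to 10.8 ± 6.40 CPM (SD, n = 5 each), a log2 fold change of −6.21 (SE 0.31, edgeR adjusted p = 2.11e-23). The largest fall was at Car11, a carbonic anhydrase-related protein of the brain (1034 ± 193 to 8.81 ± 4.53 CPM, −6.79, SE 0.31). It was followed by Pcdh1, a protocadherin (−6.62), Tuba4a, an alpha-tubulin (−6.34), Junb, an immediate early gene (−6.31), Ankrd34a (−6.31), Nptx1, a synaptic pentraxin (−6.26), and Insyn1, a protein of inhibitory synapses (−6.19). The largest rises were at Erbin (5.95 ± 3.4 to 126 ± 89.5 CPM, 4.54, SE 0.38), Tox3 (4.53), Zeb2os (4.42), Trib2 (4.23), Gas1, an Shh co-receptor (3.89), and Zeb2 (3.85). Zeb2os lies antisense to Zeb2, so their reads cannot be told apart.

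Of 46 channel genes, 36 were lower and 3 higher, with Cacna1g at −6.21 (SE 0.31), Cacna1e at −5.42 (SE 0.30) and Kcnk12 at −4.87 (SE 0.27). Camera adjusted p was 1.81e-20, and 0.0283 with an estimated correlation; with the trended scaling 34 were lower and 4 higher. Of 30 synapse genes, 20 were lower and 1 higher (21 and 1 adjusted over the list alone), with Grm4, a metabotropic glutamate receptor, at −5.58, Grin1 at −5.28, Grin2c at −5.12 and Gabrd at −5.06. Camera adjusted p was 1.56e-10, and 0.0283 with an estimated correlation; with the trended scaling 21 were lower and 1 higher. Of 20 cell cycle genes, 10 were higher and 0 lower (11 adjusted over the list alone; camera adjusted p = 0.00305, and adjusted p = 0.174 with an estimated correlation), among them Mki67 (4.94 ± 3.61 to 58.6 ± 31.1 CPM, 3.47, SE 0.38), Rrm2 (2.35), Cdc20 (2.45) and Mcm6 (2.16). With the trended scaling 9 cell cycle genes were higher and 1 lower. H3K27me3 peaks were found at 2 of 29 cell cycle TSS at P7 and at 4 at P21, so most of these rises had no peak. Among all 18089 TSS tested, 4601 were higher. Of 25 progenitor and Shh genes 11 were higher, such as Cxcr4 (2.92, SE 0.31) and Gli2 (2.81, SE 0.28), and 8 lower, such as Hes5, a Notch effector (−3.91, SE 0.26), and Cdon (−3.58, SE 0.28). The list as a whole did not pass camera (adjusted p = 0.341); with the trended scaling 15 were higher and 6 lower.

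Axon guidance and migration genes were lower at 20 of 45 TSS and higher at 7, with Epha8 at −4.94, Plxna1 at −5.02 and Slit3 at −4.69 (camera adjusted p = 0.00114, and adjusted p = 0.257 with an estimated correlation). All 39 Hox genes and 75 of 80 developmental transcription factors of other lineages were lower (2 of the latter higher), with medians of −2.17 and −2.07. Hoxb8 fell by 2.63 on the log2 scale and Gata3 by 2.69. Camera adjusted p was 7.49e-25 and 3.68e-28, and 0.174 for each with an estimated correlation. With the trended scaling 5 Hox genes were lower and 4 higher, and 13 of the transcription factors were lower and 28 higher, with medians of 0.08 and 0.16. All 39 Hox TSS kept an H3K27me3 peak at P21.

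Of 18089 TSS tested, 8846 differed, 4601 higher and 4245 lower (edgeR, BH). Most rises were at TSS without an H3K27me3 peak at P7: 3045 at TSS with neither mark then and 1182 at TSS with H3K4me3 only. With library totals the split was 12686 and 2429, with DESeq2-style size factors 5204 and 4167, with the trended scaling 2653 and 3571, and 5180 calls were shared between the trended and the TMM fit, 4814 of them in the same direction. The median of all TSS was 0.34 with TMM, 0.39 with DESeq2-style size factors and 1.42 with library totals, and by deciles of mean signal it was −2.003 in the highest and 0.87 in the lowest. Within replicates 1 and 2, which share an input, 6115 TSS differed (2474 higher, 3641 lower), and within the later replicates 4958 (1654 higher, 3304 lower). H3c10, a histone gene with near-identical copies, is uncertain, with 80 counts at P21 against 4 at P7. Tsku had 169 against 9.

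**Figure D3:**
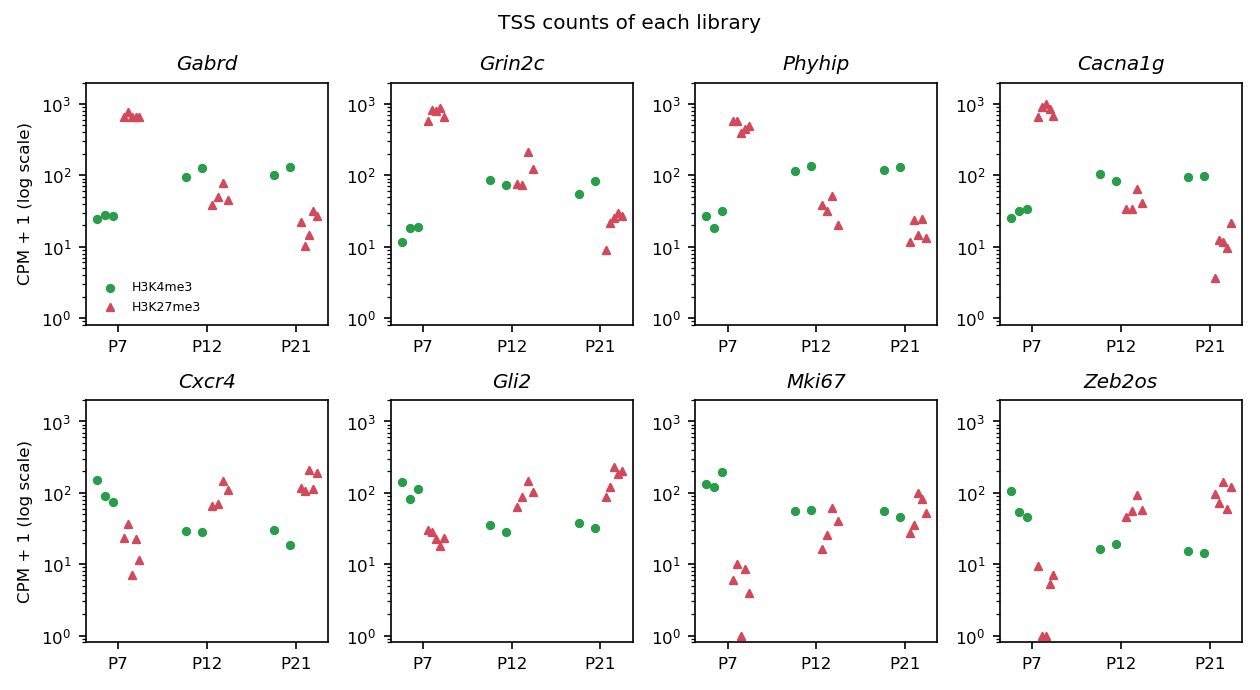
CPM plus 1 on a log scale (y axis) of each library at P7, P12 and P21 (x axis) for 8 named genes, with H3K4me3 as green circles and H3K27me3 as red triangles. At Gabrd, Grin2c, Phyhip and Cacna1g, the log2 fold change of H3K27me3 from P7 to P21 was negative (−5.06, −5.12, −4.85 and −6.21) while that of H3K4me3 was positive (2.23, 2.32, 2.27 and 1.74), and at Cxcr4, Gli2, Mki67 and Zeb2os H3K27me3 rose (2.92, 2.81, 3.47 and 4.42) while H3K4me3 fell (−2.34, −1.78, −1.63 and −2.40).

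From P7 to P12, H3K27me3 fell at most channel and synapse genes. The largest falls were at Cbarp, a regulator of calcium channels (516 ± 123 to 22.6 ± 14.9 CPM, SD, n = 5 and 4, log2 fold change −4.46, SE 0.31, edgeR adjusted p = 9.68e-17), Junb (−4.37), Fabp3, a fatty acid-binding protein (−4.37), Hr (−4.33) and Cistr (−4.31). The largest rises were at Tox3 (4.79, SE 0.50), Btbd1 (3.89), Pard3, a polarity protein (3.88), and Zeb2os (3.79), and at Timm13, where 63 counts at P12 stood against 5 at P7. Of 46 channel genes 36 were lower and 2 higher, with Cacna1g at −4.24, Cacna1e at −3.76 and Kcnh1 at −3.39, and of 30 synapse genes 20 were lower and 2 higher, with Grm4 at −4.26, Grin1 at −3.94 and Gabrd at −3.68.

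Both lists passed camera (adjusted p = 1.35e-19 and 2.61e-10, and 0.0351 and 0.0224 with an estimated correlation). Of 20 cell cycle genes 7 were higher, led by Mki67 (2.82) and Rrm2 (1.73), and 1 lower (camera adjusted p = 0.00630, and 0.208 with an estimated correlation). With the trended scaling 6 cell cycle genes were higher and 0 lower, and H3K27me3 peaks were found at 3 of 29 cell cycle TSS at P12. Of 25 progenitor genes 8 were higher, such as Gli2 (2.14) and Gas1 (3.31), and 7 lower (4 without P12 replicate 4), such as Hes5 (−2.49). All 39 Hox genes and 74 of 80 other-lineage transcription factors were lower, with 1 of the latter higher (camera adjusted p = 5.53e-20 and 6.35e-22, and 0.208 and 0.218 with an estimated correlation); with the trended scaling 2 Hox genes were lower and 2 higher, and 7 of the factors were lower and 22 higher. In all 6592 TSS differed, 2609 higher and 3983 lower. With library totals the split was 11667 and 2077 (median of all TSS 1.14 against 0.18), with DESeq2-style size factors 3775 and 3734 (median 0.30), and with the trended scaling 2047 and 2904. Within replicates 1 and 2, 5565 differed (1917 higher, 3648 lower), and within later replicates 3043 (787 higher, 2256 lower).

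Between P12 and P21, isolated alike, H3K27me3 went on falling at a part of the channel and synapse genes. Large falls were found at Insyn1, from 62.9 ± 43.7 CPM (SD, n = 4) to 5.90 ± 6.85 CPM (SD, n = 5), a log2 fold change of −3.24 (SE 0.43, edgeR adjusted p = 5.30e-06), and at Rgl3 (−3.17), Nr4a1, an immediate early gene (−3.05), and Ankrd34a (−3.01). Marcksl1, a membrane-associated actin regulator of immature neurons, rose from 10.1 ± 6.91 to 50.8 ± 34.5 CPM (2.17, SE 0.35), and Sox9 (2.05, SE 0.34), Abr (1.77) and Dbn1, an actin-binding protein (1.69), rose too. The call of Dbn1 was lost with no input arrangement (1.75, adjusted p = 0.0508), within replicates 1 and 2 (2.28, 0.0687) and within later replicates (1.48, 0.106). H2bc7 rose by 2.50 but is 1 of many near-identical histone genes, with 47 counts at P21 against 8, and its call was lost without P12 replicate 1, 2 or 3 (2.21, 2.41 and 2.69) and within later replicates (1.84).

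Of 46 channel genes 13 were lower and 1 higher (16 and 2 adjusted over the list alone), with Kcnk12 at −2.22, Hcn2, a pacemaker channel, at −2.65 and Kcna2 at −1.82. Of 30 synapse genes 7 were lower and 0 higher (12 and 0 adjusted over the list alone), with Grin2c at −2.47, Gabrd at −1.38, Grin1 at −1.33 and Chn2 at −1.22; without P12 replicate 3 the calls of Gabrd (−1.09, adjusted p = 0.0507) and Chn2 (−0.88, 0.185) were lost and 2 synapse genes were lower. The calls of Gabrd (−1.44), Grin1 (−1.31) and Chn2 (−1.35) were also lost within later replicates, and that of Chn2 within replicates 1 and 2 (−1.12). Camera adjusted p was 6.30e-12 and 1.07e-05, and 0.131 for each with an estimated correlation; with the trended scaling 13 and 9 were lower, and the adjusted p with an estimated correlation was 0.0452 and 0.0370. Among progenitor and Shh genes, Mycn, a target of Shh (1.52), and Ccnd2 (1.21, but 0.99 with adjusted p = 0.106 without P12 replicate 4 and 1.01 with adjusted p = 0.0549 with the trended scaling) were higher and 3 of 25, Cdon (−1.64) and Hes5 (−1.42) among them, were lower. Within replicates 1 and 2 the calls of Mycn (1.73), Ccnd2 (0.87), Cdon (−0.81, adjusted p = 0.293) and Plxna1 (−2.38) were lost, and within later replicates those of Mycn (1.40) and Ccnd2 (1.34). Slit3 (−2.29), Epha8 (−2.22), Sema3f (−1.49) and Plxna1 (−2.06) fell among 45 axon guidance genes, of which 1 rose. Hox genes were lower at 2 of 39 TSS, Hoxb9 (−0.92) and Hoxc5 (−0.81), at 7 without P21 replicate 3, and at 27 adjusted over the list alone. The call of Hoxb9 was lost in 8 of the alternative analyses, among them the trended scaling (−0.39, adjusted p = 0.0691) and without P12 replicate 2 or 3 or P21 replicate 1 or 2 (−0.94 to −0.69). That of Hoxc5 was lost in 11, among them without P12 replicate 1, 2 or 3 or P21 replicate 1, 2 or 4 (−0.85 to −0.59). The Hox median was −0.56 with TMM and −0.01 with the trended scaling. Of 80 transcription factors of other lineages 5 were lower and 1 higher (34 and 1 adjusted over the list alone), and between 0 (without P12 replicate 3 or P21 replicate 1) and 13 (without P21 replicate 3) were lower with a library left out. Cell cycle genes had 0 of 20 called by edgeR, with a median of 0.33 (camera adjusted p = 0.0253, and 0.276 with an estimated correlation).

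In all 719 of 18089 TSS differed, 166 higher and 553 lower (edgeR, BH). The split was 141 and 700 with DESeq2-style size factors, 365 and 607 with library totals, and 535 and 865 among TSS with a peak. Library totals moved the median of all TSS from 0.05 to 0.18. In DESeq2, which gave an adjusted p for 6248 TSS only, the split was 163 and 992. Within replicates 1 and 2, 843 differed (83 higher, 760 lower), and within later replicates 254 (5 higher, 249 lower). Without P12 replicate 3 there were 416 calls.

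**Figure D4:**
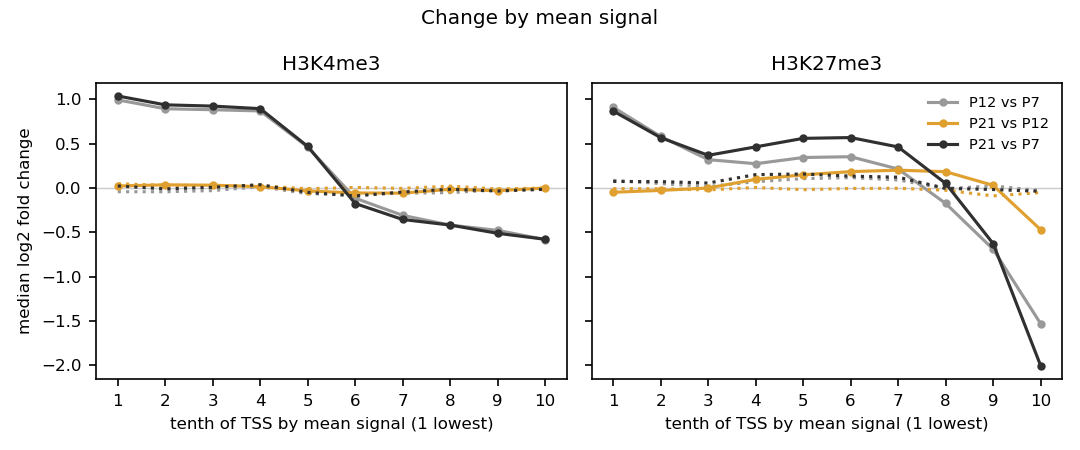
Median log2 fold change (y axis) in deciles of TSS ranked by mean signal (x axis, 1 lowest) for H3K4me3 (left) and H3K27me3 (right), with 1 color per contrast, solid lines for TMM and dotted lines for the trended scaling. With TMM the P21 against P7 median ran from 1.04 to −0.58 for H3K4me3 and from 0.87 to −2.003 for H3K27me3, while the trended medians of that contrast lay between −0.09 and 0.04 and between −0.04 and 0.16.

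Both marks changed between P7 and P21 at 1725 of 16786 TSS tested in both. H3K4me3 rose and H3K27me3 fell at Phyhip (2.27 and −4.85), Gabrd (2.23 and −5.06), Rap1gap (2.10 and −4.18), Rtn4rl1 (1.83 and −5.81) and Sowahb (1.81 and −4.83). The opposite change was found at Cd24a, a surface protein of immature neurons (−2.19 and 3.17), Cxcr4 (−2.34 and 2.92), Pcdh18 (−2.02 and 3.13), Ebf3 (−2.15 and 2.17), Zeb2os (−2.40 and 4.42) and Tshz2 (−1.87 and 2.59). Both marks fell at Pax6, a transcription factor of progenitors (−1.28 and −1.61), its overlapping transcript Pax6os1 (−1.63 and −1.51), Mab21l1 (−1.63 and −1.48), Prdm8 (−1.45 and −1.27), Barhl2 (−1.15 and −1.95) and Sstr2 (−1.08 and −1.15). With library totals the H3K27me3 call was lost at Pax6 (−0.55), Pax6os1 (−0.42), Mab21l1 (−0.39), Prdm8 (−0.22) and Sstr2 (−0.07; adjusted p between 0.0785 and 0.786), and among TSS with a peak at all of these but Pax6. The H3K4me3 calls of Prdm8 (−0.96, adjusted p = 0.0865) and Sstr2 (−0.59, adjusted p = 0.0940) were lost with the trended scaling. Both marks rose at the vomeronasal receptor genes Vmn1r258, Vmn2r-ps60, Vmn1r160, Vmn1r257 and Vmn1r148 and at Sprr2a3, all of multi-copy families without a peak of either mark, so that these are uncertain.

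H3K4me3 rose and H3K27me3 fell at 426 TSS (422.5 for independent calls), and the reverse held at 701 (466.9 for independent calls). Both rose at 455 (477.9) and both fell at 143 (412.8). With the trended scaling 640 TSS changed in both marks, 440 with H3K4me3 higher and H3K27me3 lower (107.1 for independent calls), 127 with the reverse (47.8), 52 with both higher (83.5) and 21 with both lower (61.4). At an FDR of 0.01 with TMM, 453 changed, 157 with H3K4me3 higher and H3K27me3 lower (68.9 for independent calls) and 222 with the reverse (109.5). In DESeq2 1187 of 11154 changed, 134 (46.5) and 878 (554.3) in these directions. Across TSS, which are not independent replicates, Pearson's r of the changes was −0.079 and Spearman's rho −0.051, and −0.302 and −0.203 with the trended scaling and −0.49 and −0.458 in DESeq2. Between P12 and P21, 0 TSS changed in both marks in edgeR or DESeq2, since H3K4me3 had 0 calls (206 and 57 at an unadjusted p under 0.05).

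Changes by P21 were counted by class at P7. The classes rest on peaks of the P7 libraries from which the changes are measured. This favors falls at TSS with a peak and rises at TSS without. The counts therefore do not test whether a class changed more than other TSS. For H3K27me3, where 4245 of all 18089 TSS were lower and 4601 higher, 1643 of 2698 TSS with both marks at P7 were lower and 224 higher (1425 and 398 with the trended scaling). Of TSS with H3K27me3 only at P7, 2118 of 3398 were lower and 133 higher, and with the trended scaling 1323 were lower and 602 higher. Of TSS with neither mark at P7, 279 of 8343 were lower and 3045 higher (473 and 1161 with the trended scaling). Of TSS with H3K4me3 only, 200 of 3606 were lower and 1182 higher (346 and 480 with the trended scaling). For H3K4me3, 2980 of all 20748 TSS were lower and 1864 higher. At TSS with both marks at P7 it was lower at 462 of 2905 and higher at 120, but with the trended scaling it was lower at 103 and higher at 271. At TSS with H3K4me3 only at P7 it was lower at 2352 of 6859 and higher at 32 (584 and 68 with the trended scaling).

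The size of the peak sets was compared last. H3K4me3 lists held 10990 ± 2151 peaks at P7 (SD, n = 3), 7882 ± 444 at P12 (n = 2) and 8153 ± 2735 at P21 (n = 2), with exact two-sided permutation p = 0.2 for P12 against P7, 0.3 for P21 against P7 and 1 for P21 against P12. The smallest p these designs allow is 0.1, 0.1 and 0.333. They covered 22.6 ± 8.63, 11.6 ± 0.90 and 13.1 ± 6.72 Mb. H3K27me3 lists held 23793 ± 10105 (n = 5), 20070 ± 15183 (n = 4) and 28705 ± 20770 peaks (n = 5), covering 120 ± 66.7, 92.7 ± 81.4 and 124 ± 94.9 Mb, and exact p lay between 0.484 and 0.944 for the 6 comparisons. Within replicates 1 and 2 the mean number was 13359, 7401 and 6441 at P7, P12 and P21, and within later replicates 30749, 32740 and 43548; the exact p within either set was 0.1 or more, and neither can reach 0.05. The difference between P21 and P7 in covered bases of H3K27me3, 3.84 Mb, turned negative without P21 replicate 3 (−21.6 Mb). It was also negative without P21 replicate 4 or 5 or P7 replicate 1, 2 or 3. The difference in peak number between P21 and P12 for H3K4me3, 271, was −1663 without P21 replicate 2 and also negative without P12 replicate 2.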

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

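The tests of signal over background, of isolation, and of peaks and counts from different libraries were chosen after the results were seen; the tests of class changes in all libraries and of other splits of the libraries were planned.

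H3K27me3 fell from P7 to P21 at channel genes (median log2 fold change −2.51) and synapse genes (−1.66). Lower contrast of signal over background in the later libraries is argued against as the whole cause: compared with TSS of similar mean signal the medians were −2.06 and −1.88, and no P21 library overlapped a P7 library in the members' median (exact permutation p = 0.00794 for each, n = 5 and 5). The difference in isolation is argued against as the whole cause, since between P12 and P21, isolated alike, the medians were −0.52 (exact permutation p = 0.0476, libraries of the stages overlapping) and −0.63 (exact permutation p = 0.00794, no overlap), n = 5 and 4. A part played by either stays open. The exact tests count replicates 1 and 2 of a stage, which share an input, as separate libraries. Their counts differed little beyond counting error, so they may not be independent. The chi-square per degree of freedom between them was 1.40, 1.19 and 1.33 at P7, P12 and P21, against 1.61 or more for other H3K27me3 pairs. It was also 1.19 between P12 H3K4me3 replicates 1 and 2, which have separate inputs. This measure rises with the depth of the libraries, so it does not settle whether replicates that share an input are independent. The stage of the cells is the biological difference that the design names, and it may contribute, but it was not tested apart from isolation in the comparisons with P7.

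All 39 Hox genes, and 75 of 80 transcription factors of other lineages, were called lower in H3K27me3 at P21 than at P7 with TMM. With the trended scaling the Hox median was 0.082, so that a fall of H3K27me3 and a lower contrast in the later libraries cannot be told apart. What keeps this open is that 38 of 39 Hox genes and 72 of 80 of the factors lie in the top decile of signal, whose median was −2.003 with TMM, and the trended scaling removes by construction a fall shared by TSS of such signal, whatever its cause; of channel and synapse genes 17 of 46 and 5 of 30 lie there. A change with stage may be present in addition, and was not tested.

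TSS with both marks at P7 mostly had peaks of 1 mark or neither at P21. For TSS that kept 1 mark, fewer peak calls without a change of H3K27me3 counts are argued against. With H3K27me3 peaks of replicates 1 and 2 and counts of later replicates, 628 such TSS had H3K4me3 only at P21 and 295 H3K27me3 only. The median signal of the former, less that of the latter, fell by 3.01 from P7 to P21 with no overlap of libraries (exact permutation p = 0.1, n = 3 and 3, the smallest that this design allows). TSS with neither mark at P21 were not in this test. In all libraries the medians of the change differed by −2.02 for H3K27me3 and 0.39 for H3K4me3, but this decides nothing: the groups were defined by peaks of the libraries counted, for which the bounds set beforehand made no allowance. Fewer peak calls and a change of H3K4me3 cannot be told apart. Stage and isolation may each contribute to the changes from P7.

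The numbers of H3K27me3 calls were compared with those from 33 of the 126 possible splits of the libraries, the real split included. Of these 33, only 1, the real split, gave as many in each contrast. Chance is not excluded by this. Other splits mix libraries of stages that differ, which widens the spread within groups and lowers their counts, and the remaining splits were not fitted. The real values were 6592, 719 and 8846 for P12 against P7, P21 against P12 and P21 against P7. The highest of the other splits gave 1608, 417 and 0. The splits with 1608 and 417 nearly exchanged the stages, with 0 P12 libraries and 1 P21 library kept in the group of that stage, so they carry the stage difference.

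In 3 groups 1 library passed the bound for an outlier. The ratio of the 95th percentile of H3K27me3 counts to the median was 45.0 in P7 replicate 3 and between 22.1 and 27 in the other P7 libraries; Car11 had 1367 CPM of H3K27me3 in P7 replicate 2 against 914 to 1037 CPM, and Timm13 had 22.4 CPM in P12 replicate 1 against 17.8 to 18.01 CPM. Timm13 rests on 63 counts in all P12 libraries. Chance gives such a value in about 1 in 20 groups, and here 1 of 18 groups of library measures and 2 of 93 groups of 31 genes had one. Without P7 replicate 3 the H3K27me3 calls numbered 9128 in P21 against P7.

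Peaks were called in the input libraries, which enter the comparisons only in the alternative without peaks that overlap the input. Of 18 inputs, 8 had many: 65790, 35722 and 8804 in P7 replicates 3, 4 and 5, 86149 and 55777 in P12 replicates 3 and 4, and 54511, 63706 and 9159 in P21 replicates 3, 4 and 5, against 224 to 418 in the others. No explanation was tested.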

How the results depend on the processing

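The trended scaling and the restriction to TSS with a peak were chosen after seeing the data. Of 348 alternative values of the counts, sizes and list tests, 247 counted as the same, 84 moved and 17 reversed, and the cause was not tested unless given. For numbers of changed TSS and list tests, the same means a similar total, whatever its split. H3K4me3 in P21 against P7 with library totals is thus included (4028 calls, 2549 higher and 1479 lower). For peak set sizes it means the same sign and side of the threshold, whatever the size. The H3K4me3 peak number difference of P21 against P12 is thus included with the upper part by score (27.5). Of 6828 alternative values of 318 changes at named genes, 6335 kept their direction and side of the threshold, 480 fell short of it and 13 reversed.

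Numbers of changed TSS are given as P12 against P7 and P21 against P7 for H3K4me3 (3018 and 4844), and as P12 against P7, P21 against P12 and P21 against P7 for H3K27me3 (6592, 719 and 8846). A minimum log2 fold change of 1 gave 1760 and 2611 for H3K4me3, by construction. Fitting only the compared stages gave 1958 and 3149, with fewer libraries to estimate the spread, and 1287 for H3K27me3 in P21 against P12. The block for replicate number gave 680 and 1310 for H3K4me3. Whether equal numbers mark libraries prepared together is not stated in the labels and was not settled. The trended scaling gave 695 and 1338, and 640 TSS changed in both marks; an FDR of 0.01 gave 453. With TSS with a peak only, counts were 641 and 1101 for H3K4me3 and 4200, 1400 and 5075 for H3K27me3. DESeq2 gave 3226 of 11315 for H3K4me3 in P21 against P7 and 1155 of 6248 for H3K27me3 in P21 against P12. Library totals gave 13744 and 15115 for H3K27me3 in both comparisons with P7. Summing P21 replicates 1 and 2 gave 6493, 566 and 8315 for H3K27me3. Replicates 3 and later gave 3043, 254 and 4958, while replicates 1 and 2, with fewer libraries still, gave 5565, 843 and 6115. A fit with no input arrangement gave 365 in P21 against P12.

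Leaving out a library gave 69 to 8191 and 660 to 11444 changed TSS for H3K4me3 (lowest without P12 replicate 2 and P21 replicate 1, highest without P7 replicate 2), and 4821 to 7118, 416 to 945 and 7687 to 9128 for H3K27me3. Where 1 library was left in a group, it was assumed to vary like the others. TSS with both marks numbered 1970 to 3122 at P7, 190 to 836 at P12 and 208 to 1218 at P21, and bivalent regions 1661 to 3100, 199 to 879 and 207 to 1373.

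Bivalent regions and TSS at P7, P12 and P21 were 851, 114 and 41 and 1040, 125 and 60 with the upper part by score of lists with scores, the H3K27me3 lists of replicates 3 and later being kept whole. They were 878, 141 and 18 and 896, 138 and 21 with peaks in every library, and 1932, 141 and 18 and 1748, 138 and 21 with H3K27me3 replicates 1 and 2 only. Without peaks that overlap the input they were 183 and 188 at P12 and 116 and 154 at P21, and with an overlap of 50% the TSS numbered 1626, 189 and 116.

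Differences in H3K27me3 peak number and covered Mb reversed with the upper part by score, where only replicates 1 and 2 have scores: −501.5 and −2.73 Mb for P21 against P12, and −3260 and −22.9 Mb for P21 against P7, which was −10.9 Mb without peaks that overlap the input. Leaving out a library, H3K4me3 peak numbers differed by −4266.5 to −2142 (P12 against P7), −1663 to 2205 (P21 against P12) and −4771 to −902.7 (P21 against P7), and by −15.1 to −6.52, −3.16 to 6.34 and −14.2 to −4.67 Mb. For H3K27me3 the ranges were −9573 to 823.3, 3255.5 to 14485 and −467.2 to 10478, and −63.1 to −3.61, 6.15 to 66.9 and −21.6 to 28.8 Mb.

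Of the lists past camera's threshold, 4 and 6 for H3K4me3 became 0 and 0 with an estimated correlation and 1 and 1 with fry. For H3K27me3, 10, 7 and 9 became 2, 0 and 2 with an estimated correlation; fry gave 4 in P21 against P12, and the trended scaling gave 6 in P12 against P7.

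Named H3K27me3 falls reversed with the trended scaling at Nes (0.14), Fgfr3 (0.37), Olig2 (0.077) and Cldn5 (0.11) in P12 against P7, and at Lhx5 (0.044), Gad1 (0.079), Slc6a5 (0.00), Nes (0.42) and Cldn5 (0.37) in P21 against P7. Library totals reversed C1qc in P12 against P7 (0.10) and C1qa in P21 against P7 (0.42), and so did the restriction to TSS with a peak (0.001 and 0.31).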

Other observations

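The lists of other cell types and of writers and erasers were planned, and the trended scaling was chosen after seeing the data. Their values are given without an explanation.

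H3K27me3 was lower at P21 than at P7 at Cbx7 (log2 fold change −4.05, SE 0.29) and Cbx2 (−2.52, SE 0.31). It was also lower at P21 than at P12 at Cbx7 (−1.32, SE 0.32), but not called without P12 replicate 3 (−0.71, adjusted p = 0.409), within replicates 1 and 2 (−0.91, adjusted p = 0.354) or with no input arrangement (−1.29, adjusted p = 0.0531). Of 17 writers and erasers tested for H3K27me3, 8 were lower and 3 higher (0 higher and 7 lower with the trended scaling; camera adjusted p = 0.0737).

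All 9 markers of unipolar brush cells and cerebellar nuclei were lower in H3K27me3 at P21 than at P7 (camera adjusted p = 3.54e-10, and 0.0557 with an estimated correlation; 7 lower with the trended scaling), led by Calb2 (−3.93, SE 0.27), which is also in the synapse list. For H3K4me3 1 of 7 was higher, Calb2 (1.70, SE 0.34; 1.35 and adjusted p = 0.0669 without P21 replicate 1), and 1 lower, Eomes (−0.79, SE 0.30). The call of Eomes was lost in 10 of the alternative analyses, among them without P7 replicate 1, P12 replicate 1 or 2, or P21 replicate 1 or 2 (−0.91 to −0.66) and the trended scaling (−0.46, adjusted p = 0.331).

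For H3K27me3 in P21 against P7, markers of GABAergic interneurons were lower at 12 of 14 TSS and higher at 2, Kit among them (2.72, SE 0.27). The trended scaling gave 3 lower and 5 higher. Purkinje cell markers were lower at 8 of 14 and higher at 4, Skor2 falling by 2.33 (−0.07 with the trended scaling). Astrocyte and Bergmann glia markers were higher at 7 of 19 TSS and lower at 7 (11 and 3 with the trended scaling), with Sox9 at 3.75 (SE 0.41) and Id3 at −2.42 (−0.19 with the trended scaling). Oligodendrocyte markers were lower at 9 of 18 and higher at 2 (5 and 2 with the trended scaling), endothelial and mural markers were higher at 5 of 15 and lower at 5 (8 and 3), with Esam at −3.99, and microglia markers were higher at 3 of 16 and lower at 1 (1 and 2).

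For H3K4me3 in P21 against P7, astrocyte and Bergmann glia markers were lower at 6 of 18 TSS (2 with the trended scaling, 3 without P7 replicate 1, P12 replicate 2 or P21 replicate 2, and 1 without P21 replicate 1), led by Sox9 (−1.79, SE 0.38; −1.50 and adjusted p = 0.0664 without P21 replicate 1) and Vim (−1.14, SE 0.26). Calls were few among markers of Purkinje cells (Foxp2 and Itpr1 lower, of 12), GABAergic interneurons (Pvalb higher, Kit and Lhx1 lower, of 13), oligodendrocytes (Mog higher, of 14) and microglia (C1qb and Spi1 higher, of 11). All of them were lost without P21 replicate 1 (−0.91, −0.88, 1.19, −0.77, −1.07, 1.48, 1.298 and 1.83), all but that of Itpr1 without P21 replicate 2, and all but that of Lhx1 with the trended scaling. Those of Pvalb, Kit, Lhx1 and Mog were also lost without P12 replicate 1 or 2 or P7 replicate 3, and those of Itpr1, Pvalb, Kit, Mog and C1qb without P7 replicate 1. Of 15 endothelial and mural markers edgeR called 0, and of 62 transcription factors of other lineages 3 were higher and 5 lower. For the Purkinje and GABAergic lists the median (0.02 and 0.00) and camera's direction (lower) differ in sign.

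Peaks of the inputs of replicates 3 and 4 lay over H3K4me3 consensus regions at 8.98% to 10.9% of peaks (1.71% to 2.11% for peaks placed at random), and over TSS windows at 12.1% to 13.9% (3.06% to 3.82%). In the inputs of replicate 5 these shares were 1.16% at P7 and 0.306% at P21 (1.53% and 1.32% at random), and 2.10% and 1.92% (2.77% and 2.36%).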
